A study of Gallus gallus with 20 samples.

How the data were processed

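RNA was measured in pectoralis major, the breast muscle, and in liver of male broiler chickens of a Ross strain at post-hatch day 35. The birds ate a diet with L-methionine or a diet deficient in it between weeks 3 and 5 of age. Each of the 4 groups formed by tissue and diet held 5 libraries. Per the labels there were 5 control and 5 deficient birds, so the libraries of 1 tissue were taken as separate birds. The labels do not say whether the breast and liver libraries of the same number came from the same bird.

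The deposited files hold, for each library, FPKM per gene and FPKM per isoform in the tracking format of Cufflinks, for 17108 genes and 17942 transcripts of the galGal4 assembly. The authors named TopHat2 2.0.9, Bowtie 1.0.0, Cufflinks 2.1.1 and Cuffdiff 2.1.1 without giving the role of each. Per the file headers the isoform files also give coverage, a signal of mean read depth over the transcript, and the transcript length in bases. The deposited length served, with the coverage, to estimate assigned bases and to find short features. No file gives read counts, so the number of reads per library is unknown and no count model was fitted. Estimates marked as failed are listed at 0. They covered ALB in all liver libraries, GAPDH in 7 of 10 breast libraries, and ACTA1 and ACTN1 in 1 breast library each, and these genes were left out of the tissue concerned. No identifier had more than 1 entry in a file.

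Within each tissue the FPKM values were scaled by the median ratio to the geometric mean over genes above 0 in every library. Genes with a mean scaled FPKM of at least 1 over the 10 libraries of the tissue were tested on the log2(scaled FPKM + 1) scale. Log2 changes and folds below are on that scale, as deficient minus control, and understate the change of genes near or below an FPKM of 1. Linear models with a mean-variance trend were fitted in limma 3.58.1 under R 4.3.3, 1 per tissue, with diet as the only term. A further fit over the 20 libraries tested the liver effect minus the breast effect for genes that passed the filter in both tissues. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested.

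The 50 gene lists, 37 for pathways and complexes and 13 for markers of cell types, were written before the data were examined. So were the comparisons, the threshold, the rule for named genes and the alternatives not marked as later additions. Of 1506 list entries, 1242 were found in the files by symbol, 51 of them by an older or alternative symbol. Lists with at least 5 tested genes were tested by camera in limma with a preset correlation of 0.01, which asks whether a list ranks apart from the other genes. Camera with an estimated correlation, fry by its directional p and an exact permutation of the list score were run beside it. The list score is the mean log2 value of the members in a library. For the exact permutation of the list score over all lists, the mean of all genes tested in that library was first subtracted. Scores of cell types, of lists added later and in the figure of list scores are without this subtraction. An exact test over the 252 labelings of 10 libraries cannot go below p = 0.00794.

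The text names genes by a fixed rule. In each tissue it takes the 8 largest rises and the 8 largest falls with a symbol among called genes. Where fewer than 5 genes are called in a direction, it takes the 5 with the smallest unadjusted p in that direction. It adds a panel of methionine and amino acid genes (MAT1A, BHMT, MTR, CBS, CTH, GNMT, AHCY, CDO1, ASNS, CHAC1, FGF21 and IGF1) where tested. From each list that camera calls or that holds a called gene it takes up to 4 members with the smallest p. For the tissue difference it takes the 5 called genes with the largest positive and the 5 with the largest negative value. Not every gene that the rule takes is named in the text, and some are not reported here.

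Diet effects in the tissues were compared across genes by Pearson and Spearman correlation. The reference was the correlation after permuting the diet labels within each tissue in 100 draws. Regroupings of the libraries, also 100 per result, gave the counts that other groupings of the same libraries produce.

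The alternatives covered other scalings (none, upper quartile, quantile normalization), a pseudocount of 0.1 and other filters on low values. They also covered failed estimates kept as listed, other variance models, library weights, isoform values, a replicate block, other thresholds and the removal of each library in turn. Alternatives added after the data were seen left out features shorter than 200 nt, left out liver control 4 with liver deficient 1, permuted the list score, and removed each library in turn for the correlation. The procedure was tested on simulated data with the spread of these libraries. Of 50 genes changed by 1 on the log2 scale it called 82% in breast muscle and 86% in liver, with 6 false calls in each. Of 5 lists shifted upward by 0.5 camera with the preset correlation called 5 in each tissue. It also called 0 unshifted lists higher in breast muscle and 3 in liver, and calls on the lower side were not counted. Simulated genes were drawn independently of each other, so these counts do not give the rate of false list calls in the real libraries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.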

Results

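The data describe gene expression in breast muscle (pectoralis major) and liver of 5-week-old male broilers that ate a control or a methionine-deficient diet, with 5 libraries per tissue and diet. Depth was similar between diets. The mean transcript coverage per unit of FPKM was 2.08 ± 0.257 in control breast, 2.14 ± 0.231 in deficient breast, 2.62 ± 0.541 in control liver and 2.43 ± 0.209 in deficient liver (SD, n = 5 each). Coverage times length gave between 1.40 and 2.75 assigned gigabases per library. Control breast libraries had 10322 ± 180 genes at an FPKM of at least 1 and deficient breast libraries 9622 ± 333 (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0635 over 8 library values). Liver had 9970 ± 116 and 9995 ± 112 such genes (SD, n = 5 each, exact permutation p = 0.675).

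Marker genes matched the tissue labels. The median FPKM of 12 myocyte markers was between 517 and 882 in the breast libraries and between 0.0172 and 2.60 in the liver libraries. For 22 hepatocyte markers the median was between 0.0982 and 0.291 in breast and between 727 and 1292 in liver. Liver control 1 held muscle RNA, with a fast contractile score of 5.89 on the log2 scale against 1.27 to 1.47 in the other 9 liver libraries. In liver control 4 and liver deficient 1, mitochondrial genes took 63.1% and 36.1% of the FPKM sum, largely through a short mitochondrial RNA in each. Replicates correlated at Pearson values between 0.923 and 0.968 across genes, which are not independent of each other. The leading principal component of breast muscle held 34.1% of the variance and placed controls between -34.5 and -13.5 and deficient libraries between 5.07 and 39.4. In liver it held 18.9% and did not separate the diets.

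The breast muscle comparison asked which transcripts a methionine shortage alters in the tissue with the largest protein deposition in these birds. On the deficient diet, breast muscle had less RNA of immune cells, acute phase proteins and extracellular matrix, and more RNA of mitochondrial respiration, fast contractile fibres and ubiquitin ligases of muscle protein breakdown. Camera called 25 of 47 lists with its preset correlation and 0 with an estimated correlation. With the preset correlation 7 of 100 groupings of the libraries, the real one included, reached 25. Of all genes tested 12.9% were called higher and 14.6% lower, and the cell cycle (9.09% lower), tRNA synthetase (10.5% higher), fatty acid oxidation (16.1% higher), mitochondrially encoded (16.7% higher) and proteasome (18.2% higher) lists lay near or below these shares. The largest fall was that of SPP1, which encodes the secreted matrix protein osteopontin, from 149 ± 46.4 to 15.1 ± 21.4 scaled FPKM (SD, n = 5 each, 15.5-fold lower, limma adjusted p = 0.00228). The largest rise was that of CKMT2, the mitochondrial creatine kinase of striated muscle, from 166 ± 57.9 to 596 ± 180 scaled FPKM (SD, n = 5 each, 3.66-fold higher, limma adjusted p = 0.00217). In both cases all 5 deficient libraries lay beyond all 5 controls.

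Besides CKMT2 (ENSGALG00000015602, galGal4 chromosome Z, 63574950 to 63597283), the large rises included FBP2 (ENSGALG00000012612, chromosome Z, 41279377 to 41302319), the muscle fructose bisphosphatase. It went from 164 ± 45.5 to 510 ± 136 scaled FPKM, 3.11-fold higher. GLUL (ENSGALG00000003678, chromosome 8, 5614757 to 5623685), which encodes glutamine synthetase, went from 39.4 ± 11.8 to 126 ± 39.3, 3.09-fold higher. Other large rises included PROCA1 (log2 change 1.72), SLC25A30, a mitochondrial carrier (1.62), CCDC180 (1.61) and ASB2, a substrate adaptor of ubiquitin ligases in muscle (1.48). Their adjusted p ranged from 0.00335 for ASB2 to 0.0470 for CCDC180, whose call was lost when any of 8 libraries was left out, breast control 2 and breast deficient 4 among them (adjusted p = 0.0729 and 0.0928).

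After SPP1 (ENSGALG00000010926, chromosome 4, 45074192 to 45077215) the deepest fall was that of TTR (ENSGALG00000015143, chromosome 2, 105824285 to 105831740), a carrier of thyroid hormone. It went from 56.2 ± 19.3 to 6.56 ± 7.14 scaled FPKM, 9.41-fold lower. Further falls were HPS5 (-2.91), the collagen-regulating CTHRC1 (-2.71), the siderophore-binding lipocalin EX-FABP (-2.55), the protease inhibitor CSTA (-2.44), the myeloid calgranulin S100A9 (-2.32) and the pentraxin PTX3 (-2.30). Their adjusted p lay between 0.000898 and 0.0147. HPS5 is carried by 2 gene identifiers, and the other one was at 0.08 and not called, so the symbol stands for 1 short model of 552 nt here.

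**Figure D1:**
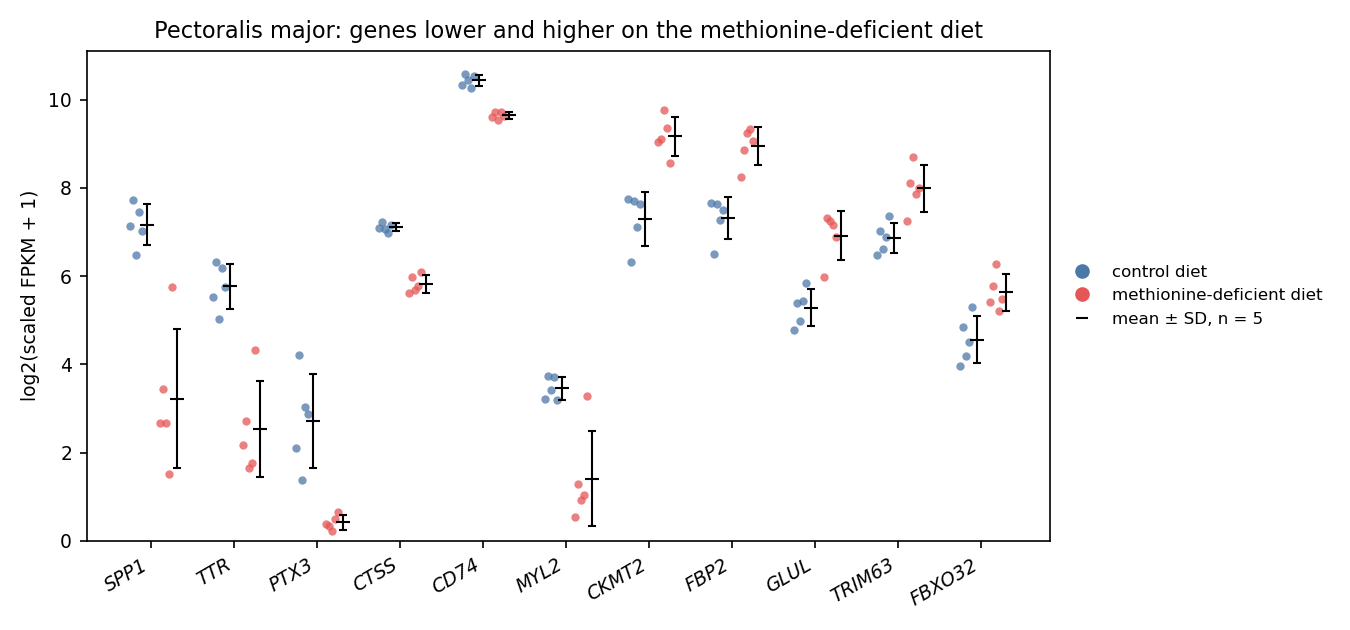
Expression of 11 genes in the breast muscle libraries, as log2(scaled FPKM + 1), with points for libraries (blue control, red deficient) and bars for the mean and SD (n = 5). SPP1, TTR, PTX3, CTSS, CD74 and MYL2 were lower on the deficient diet and the other 5 genes were higher.

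Genes of macrophages fell together in breast muscle. Of 19 tested macrophage markers 17 fell and none rose, with a median log2 change of -1.20. CTSS, the lysosomal protease cathepsin S, went from 137 ± 8.55 to 56.3 ± 8.38 scaled FPKM (SD, n = 5 each, limma adjusted p = 0.000287). MPEG1, a pore-forming protein of phagocytes, changed by -1.38, SPI1, the myeloid transcription factor PU.1, by -1.34, and the lysosomal membrane gene LAPTM5 by -1.29. Camera placed the list lower with adjusted p = 2.24e-12, and with adjusted p = 0.274 with an estimated correlation. Heterophil markers, those of the avian neutrophil counterpart, fell in 8 of 12 cases (camera adjusted p = 0.00163, and adjusted p = 0.367 with an estimated correlation). Among them were MMP9 (-1.96), the receptor CSF3R (-1.95) and NCF4 (-0.96) of the oxidant-producing enzyme complex. CSF3R also stands in the macrophage list and MMP9 in the matrix list.

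Lymphocyte markers were lower too. B cell markers fell in 5 of 7 cases, with the kinase BTK at -1.18 and the immunoglobulin joining chain IGJ at -1.57 (adjusted p = 0.00772, and adjusted p = 0.298 with an estimated correlation). T and NK cell markers fell in 5 of 15 cases, with IL2RG at -1.31, CD4 at -0.63 and CD3E at -0.62 (adjusted p = 0.00772, and adjusted p = 0.466 with an estimated correlation). The IGJ and CD3E calls each ended without any of 3 libraries, breast deficient 4 for IGJ (adjusted p = 0.0581) and breast control 2 for CD3E (adjusted p = 0.0562) among them. As a mean over members, the macrophage score differed by -1.09 and the heterophil score by -0.81 (n = 5 each, exact permutation p = 0.00794 each, adjusted p = 0.0238 over 9 cell types). B cell and T and NK cell scores differed by -0.71 and -0.40 (n = 5 each, exact permutation p = 0.00794 and 0.0159, adjusted p = 0.0238 and 0.0286). The fibroblast score differed by -0.30 (exact permutation p = 0.0317, adjusted p = 0.0476), and the myocyte score by 0.40 (exact permutation p = 0.0159, adjusted p = 0.0286). Differences were -0.01 for endothelial, -0.34 for adipocyte and 0.20 for erythroid markers (exact permutation p = 0.873, 0.214 and 0.135).

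Genes that act in immune recognition followed. Of 19 genes of antigen presentation 8 fell and 1, NLRC5, rose. CD74, the invariant chain of class II molecules, fell from 1389 ± 127 to 801 ± 44.8 scaled FPKM (SD, n = 5 each, limma adjusted p = 0.00119). The class II beta chain BLB1 changed by -0.95 and the peptide loading gene DMB2 by -1.08. Both have close relatives in the same gene cluster, and reads shared with these could not be told from their own. Inflammatory signalling genes fell in 24 of 44 cases, including the adaptor MYD88 (-0.80), the NF-kB subunit REL (-0.55) and the receptors TLR4 (-1.29) and TLR2-1 (-1.38). Interferon response genes fell in 15 of 32 cases, such as the transcription factor IRF8 (-0.65), the receptor chain IFNAR1 (-1.02), EPSTI1 (-0.93) and the RNA editing enzyme ADAR (-0.42). Complement genes fell in 12 of 18 cases, with C3AR1 at -1.55, ITGB2 at -1.54, C1QA at -1.18 and C1QB at -1.16. ITGB2, C1QA, C1QB and TLR4 also stand in the macrophage list, as does CTSS of the antigen presentation list, so these lists are not independent of it. In the acute phase list 7 of 10 genes fell, among them the iron-binding LTF (-1.27), the cytokine brake SOCS3 (-2.02) and the haem-binding HPX (-1.99). Camera adjusted p for these 5 lists were 0.000362, 1.67e-08, 3.52e-07, 3.87e-06 and 0.00138 in this order. The adjusted p = 0.222, 0.274, 0.298, 0.274 and 0.274 were found with an estimated correlation.

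Extracellular matrix genes fell in 16 of 38 cases, including the matrix protease MMP9, the adhesive glycoproteins THBS1 (-1.67) and TNC (-1.48) and the proteoglycan VCAN (-0.77). Fibroblast markers fell in 4 of 16 cases, such as COL3A1 (-0.60), and 1, RGS5, rose. Immediate early genes fell in 5 of 16 cases, with FOSL2 at -1.34, NR4A3 at -0.91 and MYC at -0.70. Cell cycle genes fell in 3 of 33 cases (MCM5, PLK1 and CDC2), 1 of them when adjusted over the list alone. The PLK1 call ended without any of 4 libraries and the CDC2 call without any of 8, breast control 2 among them for both (adjusted p = 0.0677 and 0.0922). The 6 tested genes of the hepatocyte list, TTR, LTF, HPX and APOA1 among them, are also expressed in breast muscle, and 4 of them fell, APOA1 without a call when any of 4 libraries was left out, breast control 2 (adjusted p = 0.0653) among them. Camera adjusted p were 7.05e-06, 0.0373, 0.00772, 0.00235 and 0.00772 in this order. With an estimated correlation the values were adjusted p = 0.398, 0.473, 0.404, 0.542 and 0.274. TTR, LTF and HPX of the hepatocyte list also stand in the acute phase list, so these lists are not independent.

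Genes of mitochondrial respiration rose. In the oxidative phosphorylation list 41 of 59 genes rose and 1, COX8A, fell. The complex I subunits NDUFB3, NDUFA4, NDUFA8 and NDUFS6 changed by 0.72, 0.69, 0.67 and 0.61, NDUFB3 from 113 ± 12.5 to 186 ± 16.4 scaled FPKM (SD, n = 5 each, limma adjusted p = 0.00158). In the TCA cycle list 13 of 24 genes rose and 1, ACO1, fell, with DLD at 0.78, MDH2 at 0.73, SDHB at 0.65 and SUCLA2 at 0.60. Camera adjusted p were 2.24e-12 and 7.05e-06 (adjusted p = 0.398 and 0.404 with an estimated correlation). SDHB stands in both lists, so they are not independent. The mitochondrially encoded genes MT-ND3 and ND4L rose (0.53 and 0.52), 2 of the 12 in that list, but their calls ended without any of 6 and 7 libraries, breast control 4 among them for both (adjusted p = 0.0679 and 0.111). Its camera call (adjusted p = 0.00260, and adjusted p = 0.516 with an estimated correlation) was lost under quantile normalization (camera adjusted p = 0.930). The list median was then 0.02, against 0.04 over all genes. Fatty acid oxidation genes rose in 5 of 31 cases, with the uncoupling protein UCP at 1.24 and the acyl-CoA dehydrogenase ACADSB at 0.82 (adjusted p = 0.00772, and adjusted p = 0.473 with an estimated correlation).

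Fast contractile genes rose in 11 of 13 cases, with the Z-disc genes ACTN2 (0.96) and MYOZ1 (0.78), the M-band gene MYOM2 (1.02) and the AMP deaminase AMPD1 (1.23). Slow contractile genes fell in 7 of 16 cases, with the slow myosin light chain MYL2 (-2.05), the calcium pump ATP2A2 (-0.59), MYH15 (-1.07) and TPM3 (-0.90). Camera adjusted p were 1.49e-05 and 0.00379 (adjusted p = 0.367 and 0.494 with an estimated correlation). The slow list was not called by fry (adjusted p = 0.0532) or by its score (exact permutation p = 0.0556, adjusted p = 0.0842). Breast deficient 5 stood apart from the other 4 deficient libraries for MYL2, MYH15 and TPM3. Myocyte markers rose in 9 of 12 cases and 1, LMOD2, fell (adjusted p = 0.000794, and adjusted p = 0.392 with an estimated correlation). These lists overlap, since ACTN2, MYOZ1, AMPD1 and other genes stand in both.

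Genes of muscle protein breakdown were higher. Of 17 genes linked to muscle wasting 9 rose and 1, CISH, fell. UBE2B, a ubiquitin-conjugating enzyme, went from 44.3 ± 2.06 to 69.3 ± 4.07 scaled FPKM (SD, n = 5 each, limma adjusted p = 0.00115). The ligase adaptors FBXO30 and FBXO40 changed by 0.66 and 1.31 and the deubiquitinase USP2 by 1.33. TRIM63 (MuRF1) and FBXO32 (atrogin-1), the best known ligases of muscle wasting and named for that after their values were seen, changed by 1.12 and 1.07. Proteasome genes rose in 6 of 33 cases, with PSME4 at 0.62 and PSMD4 at 0.48, and genes of amino acid breakdown in 8 of 19, with AASS at 0.93 and BCKDHB at 0.90. Of 19 aminoacyl-tRNA synthetases 2, DARS (0.40) and AARS (0.51), rose, and 0 were called when adjusted over the list alone. Their calls ended without any of 7 and 8 libraries, breast control 2 among them for both (adjusted p = 0.0840 and 0.104). Camera adjusted p were 0.000886, 0.00235, 0.00425 and 0.0375 for these 4 lists, and adjusted p = 0.353, 0.542, 0.274 and 0.561 with an estimated correlation. Without scaling between libraries the list medians of the proteasome, amino acid breakdown, tRNA synthetase and fatty acid oxidation lists were negative (-0.16, -0.05, -0.16 and -0.01), yet each stayed above the median of all genes, which shifted by -0.25.

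Of 19 methionine cycle genes 4 rose (21.1%) and 1 fell (5.26%) in breast muscle, and of 8 transsulfuration genes 2 rose (25%) and 0 fell. Over all genes 12.9% rose and 14.6% fell. Both lists are small, and their shares were not compared with these by a test. Camera did not call these lists (adjusted p = 0.321 and 0.157, and adjusted p = 0.494 for both with an estimated correlation), while the exact permutation of the list score did (adjusted p = 0.0448 and 0.0196). SHMT1 (0.34) and ALDH7A1 (0.43) of the folate and betaine steps rose, calls that ended without scaling and for ALDH7A1 also under quantile normalization, and AHCYL1 (-0.40) fell. CTH, which makes cysteine from cystathionine, rose from 16.2 ± 0.954 to 23.5 ± 4.42 scaled FPKM (SD, n = 5 each, limma adjusted p = 0.0126), a call lost without scaling (adjusted p = 0.136). BHMT, which remethylates homocysteine with betaine, was at 0.37 (adjusted p = 0.0420), a call lost under each other scaling and when any of 7 libraries was left out, breast control 2 (adjusted p = 0.104) among them. The methionine synthase MTR (-0.30), MAT1A (0.08), GNMT (-0.03), AHCY (-0.05) and CDO1 (-0.04) did not pass the threshold. Nor did the amino acid response genes ASNS (-0.22) and CHAC1 (-1.48, adjusted p = 0.149) or the growth factor gene IGF-I (0.22).

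In all, 2805 of 10178 genes tested in breast muscle were called by limma, 1314 higher and 1491 lower (46.8% higher), and 292 of them differed at least 2-fold, 74 higher and 218 lower. The diets did not overlap for 1862 genes, 18.3% where chance gives 0.794%. Without scaling 9.14% of 3522 called genes were higher, and the macrophage, oxidative phosphorylation and fast contractile lists kept their sides (medians -1.46, 0.16 and 0.46). The share was 36.4% of 2703 with upper-quartile scaling and 52.3% of 2740 with quantile normalization, and with a filter at 5 FPKM it was 59.9% of 2032 (1218 higher, 814 lower). Camera called 25 of 47 lists, 10 higher and 15 lower, and camera with an estimated correlation 0. Fry called 21, of which 19 were shared, without the cell cycle, proteasome, mitochondrially encoded, slow contractile, fatty acid oxidation and tRNA synthetase lists. The exact permutation of the list score called 25, of which 20 were shared, without the cell cycle, mitochondrially encoded, slow contractile, fibroblast and tRNA synthetase lists. Camera with the preset correlation called 19 lists without scaling (9 higher, 10 lower, 17 shared). With quantile normalization it called 21 (5 higher, 16 lower, 19 shared). Adjusted over the list alone, the counts of called genes were 17 lower for macrophage markers, 49 higher and 2 lower for oxidative phosphorylation, 20 higher and 1 lower for the TCA cycle and 11 higher for fast contractile genes. They were 25 lower for inflammatory signalling, 17 for interferon response, 13 for complement, 21 for matrix, 9 lower and 1 higher for antigen presentation, and 9 higher and 1 lower for muscle wasting. Without breast control 2 the gene count was 1804.

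**Figure D2:**
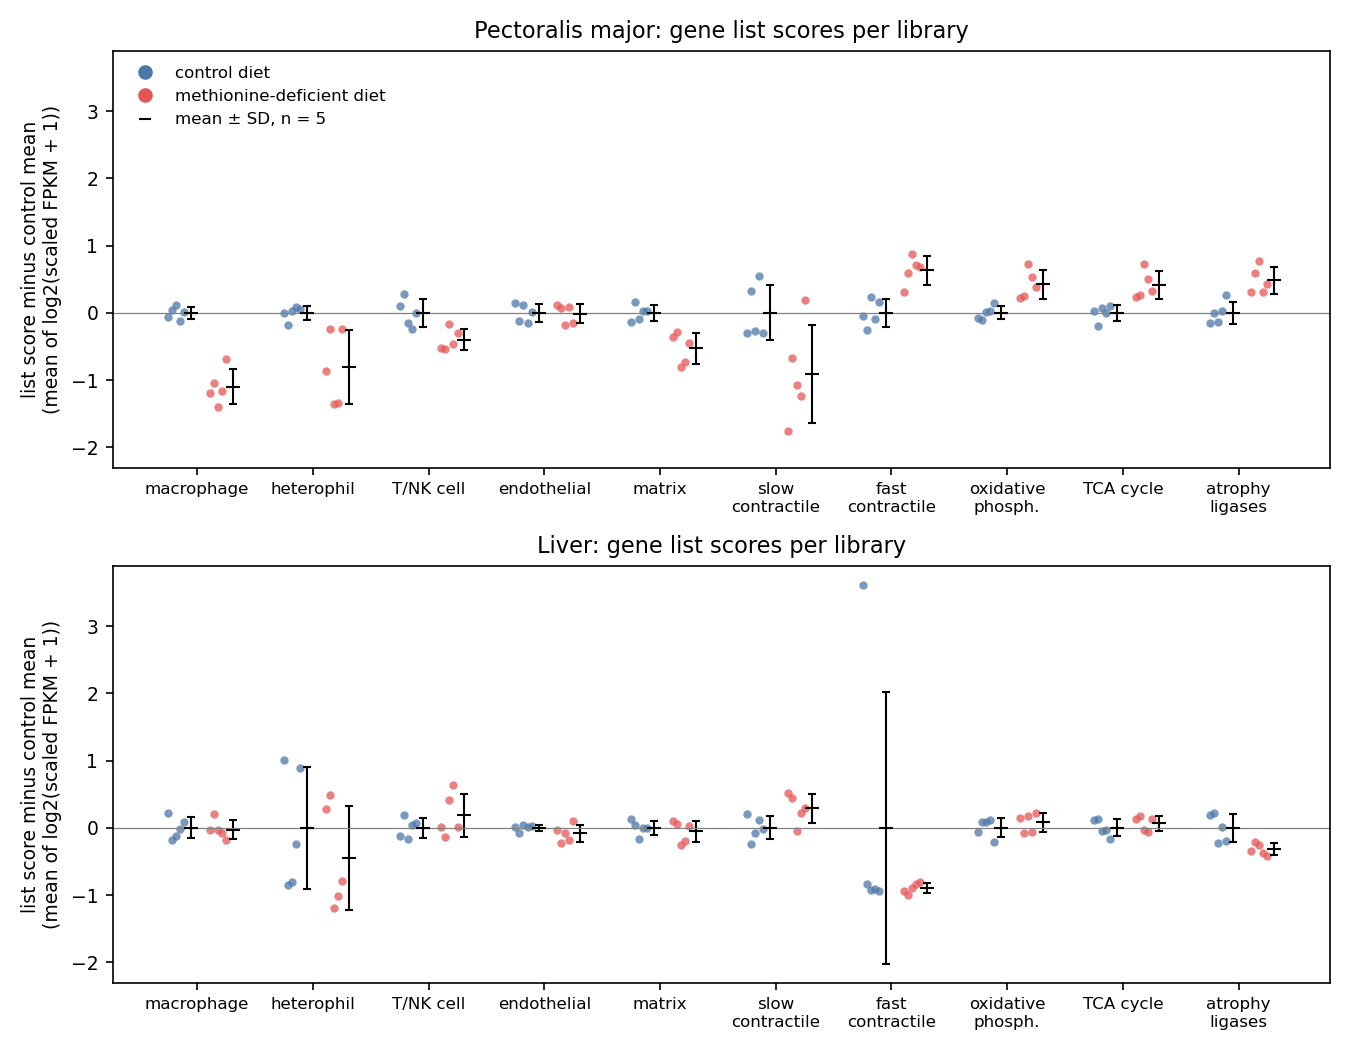
Scores of 10 gene lists in each library, as the mean log2(scaled FPKM + 1) of the members minus the mean of the 5 control libraries, for pectoralis major and liver, with points for libraries (blue control, red deficient) and bars for mean and SD (n = 5). In breast muscle all 5 deficient libraries lie below all 5 controls for macrophage, heterophil and matrix genes and above them for fast contractile, oxidative phosphorylation, TCA cycle and atrophy ligase genes, and in liver control 1 stands far above the other livers for fast contractile genes.

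The liver comparison asked the same of the organ that carries most of the methionine cycle. No gene passed the threshold there. The 3 with the smallest p were lower on the deficient diet. MIB2 (ENSGALG00000001473, chromosome 21, 2046501 to 2069501), a ubiquitin ligase, lay at 31.6 ± 3.76 scaled FPKM in controls and 16.8 ± 1.82 on the deficient diet (SD, n = 5 each, 1.83-fold lower, limma adjusted p = 0.0712), with all 5 deficient livers below all controls. The heat shock cochaperone DNAJA4 (ENSGALG00000003251, chromosome 10, 3237428 to 3243990) lay at 97.2 ± 55.2 and 19.6 ± 5.36, 4.38-fold lower. TSC22D3 (ENSGALG00000027069, chromosome 4, 1770827 to 1772689), the glucocorticoid-induced leucine zipper, lay at 183 ± 62.5 and 62.5 ± 3.99, 2.75-fold lower. Their adjusted p of 0.134 was shared by SPATA13 (-0.91) and ZBTB16 (-1.39), a further glucocorticoid-responsive gene.

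On the higher side the smallest p belonged to CCDC61 (0.54, adjusted p = 0.134), YPEL2 (0.55), GTPBP2 (0.45) and ARID3A (0.60), each of the last 3 with adjusted p = 0.229. The small nucleolar RNA SNORA40 was listed at 0 in 4 of the 5 control livers, at 16.2 scaled FPKM in liver control 2, and between 11.7 and 31.2 in the deficient livers (adjusted p = 0.229). Without liver control 2 it was called (adjusted p = 4.25e-05). The annotated feature is short, spanning 1:185065919 to 185066045. The method may recover RNA this short poorly, which was not tested.

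Enzymes of methionine metabolism were not called in liver, where moderate changes would often be missed. In the simulation 32% of changes of 0.5 on the log2 scale were called. It also held larger changes, which ease the adjusted threshold, so the share would be lower in a tissue without called genes. MAT1A, which makes S-adenosylmethionine, lay at 656 ± 132 and 644 ± 360 scaled FPKM (SD, n = 5 each, log2 change -0.21 with a standard error of 0.378). The others were BHMT (0.24), MTR (0.09), CBS (0.12), CTH (0.04), GNMT (0.02), AHCY (-0.20) and CDO1 (-0.33), with adjusted p of 0.854 or above. ASNS was at 0.11 and IGF-I at -0.08. CHAC1, a glutathione-degrading gene of the amino acid response, spread widely in controls and lay at 48.1 ± 50.1 and 6.63 ± 4.89 (-2.29, adjusted p = 0.351).

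Camera with the preset correlation placed 6 lists apart in liver without a called gene. Of 100 groupings of the libraries 91 gave at least as many, so chance was not excluded. Complement genes were lower in 22 of 26 cases with a median of -0.32, such as C8G (-0.44) and COLEC11 (-0.34). Immediate early genes were lower in 14 of 15, with SIK1 at -1.90, BTG1 at -0.66 and DUSP1 at -0.57. Muscle-wasting and ubiquitin genes were lower in 10 of 14, with KLF15 at -1.17, UBB at -1.12, FOXO3 at -0.83 and FBXO32 at -0.48. Mitochondrially encoded genes were higher in 11 of 12 (MT-CO3 0.27), oxidative phosphorylation genes in 47 of 59 (NDUFB3 0.27) and T and NK cell markers in 16 of 19 (EOMES 0.46, against IL7R at -0.47). Camera adjusted p for these 6 lists were 0.00172, 0.00893, 0.0199, 0.00615, 0.0199 and 0.0268, and adjusted p = 0.964 for each with an estimated correlation. Fry by its directional p and the exact permutation of the list score called 0 of the 49 lists. The mixed test of fry, which ignores direction, gave adjusted p = 0.00873 for the muscle-wasting list, 0.00873 for the circadian list and 0.0151 for the amino acid response list. Adjusted over the list alone, 2 muscle-wasting and ubiquitin genes were called lower and none in the other 5 lists that camera called. Without liver control 1, which held muscle RNA, only the complement and immediate early lists kept their camera calls, and the other 4 had adjusted p = 0.103.

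**Figure D3:**
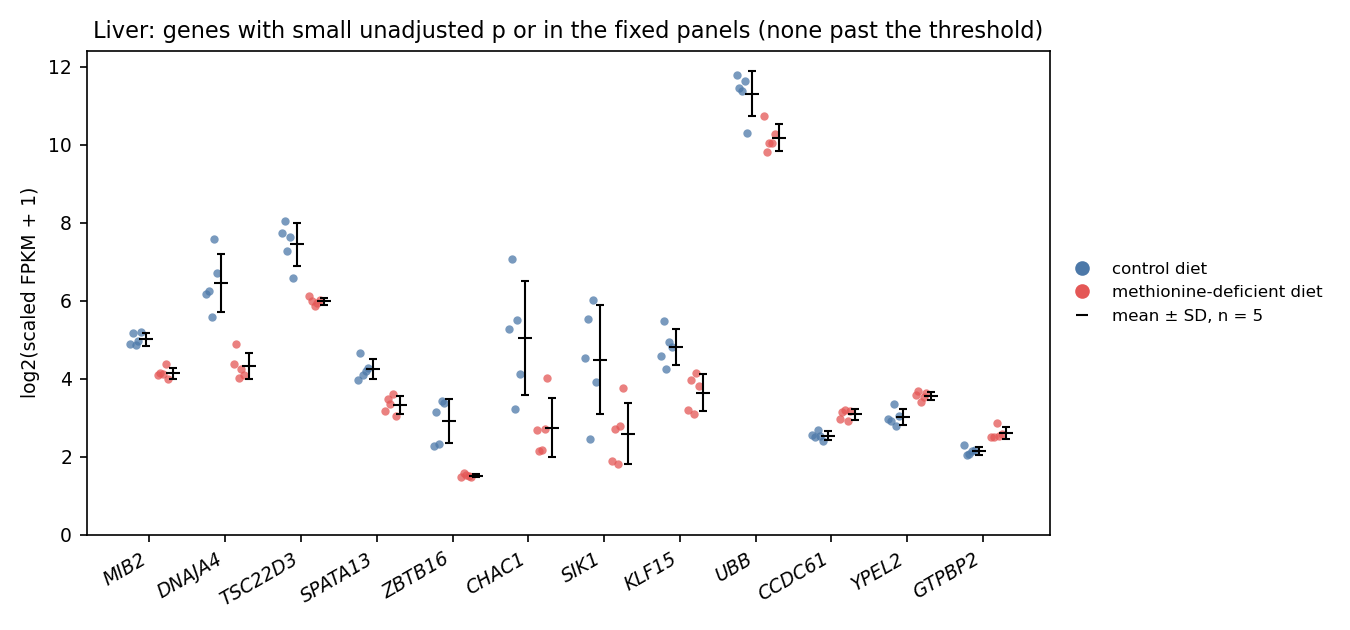
Expression of 12 genes in the liver libraries, as log2(scaled FPKM + 1) on the vertical axis, with points for libraries (blue control, red deficient) and bars for the mean and SD of 5 libraries. None of the 12 passed the threshold, and control livers spread more widely than deficient livers for DNAJA4, TSC22D3, CHAC1 and SIK1.

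Limma called 0 of 10188 genes in liver, against 849 at an unadjusted p under 0.05 (414 higher, 435 lower), where 509 are expected by chance on average. Genes are not independent of each other, and this count was not compared with regrouped libraries. The diets did not overlap for 184 genes, 1.81% where chance gives 0.794%. MIB2 was called with a filter at 5 FPKM (adjusted p = 0.0349), with no filter (0.0401) and at the isoform level (0.0373). Without liver control 3 there were 11 calls, among them MIB2, DNAJA4, ZBTB16, CREM and HSP70, and without liver control 5 the only call was TSC22D3 (adjusted p = 0.00717).

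The last comparison asked whether the diet acted differently on the same gene in the tissues. It did for a broad set of genes, and most of these were genes that changed in breast muscle. TTR differed by 3.42 and SPP1 by 3.45 between the tissues (liver minus breast, adjusted p = 0.00189 and 0.00642), with liver log2 changes of 0.19 and -0.50. CTSS and CD74 differed by 1.36 and 1.01. The other side included FST, an inhibitor of myostatin (-2.57), the lipid phosphatase LPIN1 (-2.57), PDK4, which restrains glucose oxidation (-2.17), and the ubiquitin gene UBB (-2.05). FST lay at 0.49 in breast and -2.08 in liver, LPIN1 at 0.62 and -1.95, PDK4 at 0.88 and -1.29, and UBB at 0.93 and -1.12. G0S2, an inhibitor of fat breakdown, lay at -0.66 in breast and 2.82 in liver and differed by 3.48 (adjusted p = 0.0259, and adjusted p = 0.0504 without liver control 2 and 0.0546 without breast control 2). The nucleolar RNAs SNORA40 and SNORA25 were also called (adjusted p = 0.0379 and 0.0388). SNORA25 was listed at 0 in all 5 control livers and above 0 in 4 of 5 deficient livers. SNORA40 lost its call without any of 15 of the 20 libraries and SNORA25 without any of 14, liver control 1 among them for both (adjusted p = 0.0591 and 0.0548).

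Camera called 15 of 45 lists for the tissue difference. Macrophage markers had medians of -1.20 in breast and 0.02 in liver, oxidative phosphorylation genes 0.47 and 0.07, and muscle-wasting and ubiquitin genes 0.42 and -0.17 over those tested in both tissues. Their adjusted p were 1.80e-14, 1.02e-08 and 0.000101, and adjusted p = 0.128, 0.558 and 0.268 with an estimated correlation, which called 0 of the 45 lists. The fast contractile difference (median -1.70) rests on liver values that liver control 1 set.

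**Figure D4:**
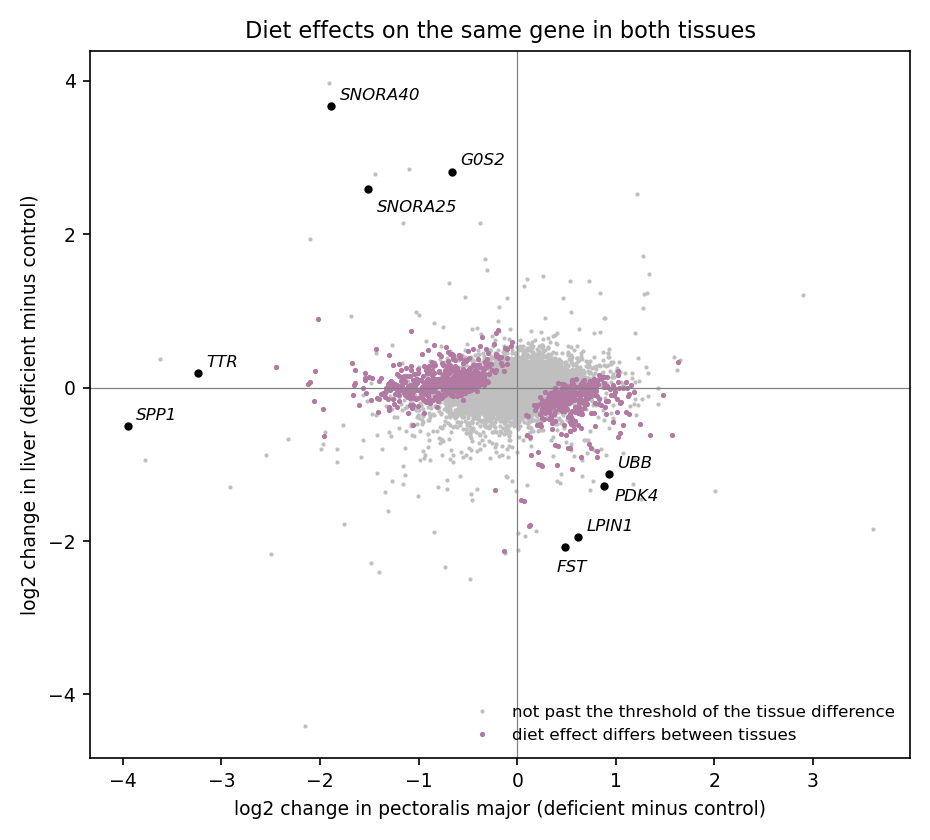
Log2 change on the deficient diet in pectoralis major (horizontal axis) against liver (vertical axis) for 9144 genes tested in both tissues. Purple points are the 839 genes whose diet effect differed between tissues, and names mark genes with the largest differences in each direction.

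Limma called 839 of 9144 genes for the tissue difference, 507 with liver above breast and 332 below, and 750 of them were also called in breast muscle. Without scaling it called 1871, 1799 with liver above, and with upper-quartile scaling 842, 625 with liver above. With a filter at 5 FPKM 273 of 557 had liver above. The count was 472 without breast control 2, 525 without breast deficient 4, 553 without breast control 4 and 558 without breast deficient 3. Across genes the diet effects correlated at Pearson r = 0.0994 (permutation p = 0.248, permuted in each tissue on its own as if the birds were separate, range -0.189 to 0.205) and Spearman correlation 0.136 (permutation p = 0.139). Of 2490 genes called in breast and tested in liver, 1460 (58.6%) had the same sign in liver, a share not compared with permuted labels.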

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

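All tests of explanations in this part were chosen after the result was seen, except the test of gene length and the regroupings of libraries. The prediction for a separate list of glucocorticoid targets was marked as written before, but the list itself was written after the data were seen. A library was singled out where its gap to the nearest of the other 4 libraries of its group as a ratio to the group's range exceeded Dixon's 95% critical value. Chance does this in about 1 of 20 groups, and 41 of 692 groups met it where 35 are due to chance, so single cases mean little. In liver, control 1 stood apart for the fast contractile list (0.977) and the myocyte list (0.947), control 2 for the endothelial list (0.749), and deficient 5 for the fibroblast list (0.730). The FPKM sum and the mitochondrial share stood apart in control 4 (0.880 and 0.840) and in deficient 1 (0.777 and 0.862). Single liver genes were SNORA40 in control 2 (a ratio of 1), UBB in control 5 (0.718), EOMES in control 3 (0.755), CD247 in control 2 (0.830), GTPBP2 in deficient 3 (0.752), ARID3A in deficient 4 (0.765) and C2 in deficient 2 (0.801).

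Among control breast libraries, control 5 stood apart for the circadian list (0.751), the ER stress list (0.743), AASS (0.745), PGD (0.792) and NDUFA4 (0.766). Control 3 did so for CCDC180 (0.874), CEBPB (0.713) and TET2 (0.784), control 2 for FABP5 (0.835) and COL14A1 (0.791), control 1 for TNC (0.870), and control 4 for CSF3R (0.836) and NOTCH2 (0.760). Breast deficient 5 stood apart for 10 genes: CSTA (0.741), TFEB (0.838), C1QB (0.804), RGS5 (0.716), FBP1 (0.880), ALDOC (0.830), LAPTM5 (0.723), MYL2 (0.726), MYH15 (0.855) and TPM3 (0.924). LTF in deficient 3 (0.728), RRM2 in deficient 1 (0.862) and FBXO30 in deficient 2 (0.786) completed the set.

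The diet effect differed between tissues, by the interaction test in limma, for 75 of 206 named genes. Liver minus breast, the higher side held SNORA40 5.56, SNORA25 4.10, G0S2 3.48, SPP1 3.45, TTR 3.42, SOCS3 2.92, CSTA 2.71, CEBPB 1.94, SULT1B1 1.82, GSTA3 1.70, ITGB2 1.67, C3AR1 1.64, TNC 1.60, THBS1 1.57, MPEG1 1.501, CEBPA 1.47, TLR4 1.36, CTSS 1.36, IL2RG 1.35, MMP9 1.34, BTK 1.32, DMB2 1.32, TLR2-1 1.29, SPI1 1.29, IGFBP4 1.27, LAPTM5 1.26, C1QB 1.23, BLB1 1.22, C1QA 1.20, SMOX 1.18, IRF8 1.08, ALDOC 1.05, CD74 1.01, FBP1 0.98, NCF4 0.96, COX8A 0.88, SMAD3 0.85, TPM3 0.85, PGD 0.79, TKT 0.77, MYD88 0.73, ARID3A 0.65, NOTCH2 0.64, COL3A1 0.64, CCDC61 0.61, ADAR 0.55, AHCYL1 0.51 and REL 0.39. The lower side held RPTOR -0.42, MBD4 -0.48, HSPA9 -0.60, FABP5 -0.66, SOX18 -0.66, PRDX3 -0.69, CRY1 -0.69, DLD -0.70, FBXO30 -0.74, UBE2B -0.76, MSRB3 -0.76, ACADSB -0.77, SIX4 -0.79, MIB2 -1.01, ADSSL1 -1.05, PFKM -1.11, GLUL -1.30, TSC22D3 -1.50, FBXO32 -1.55, ASB2 -1.57, FOXO3 -1.64, SESN1 -1.96, DNAJA4 -2.00, UBB -2.05, PDK4 -2.17, LPIN1 -2.57 and FST -2.57. List medians differed, by camera with the preset correlation, by 1.20 for macrophage, -0.38 for oxidative phosphorylation, 0.40 for inflammatory signalling, -0.75 for muscle wasting, 0.37 for matrix, -0.40 for TCA cycle, 0.42 for antigen presentation, 0.40 for interferon response, 0.60 for T and NK cells, 0.43 for complement, -1.70 for fast contractile, 1.09 for hepatocyte, 0.83 for B cells, 0.85 for heterophils and 0.99 for acute phase genes. None of the 15 was called with an estimated correlation (adjusted p between 0.128 and 0.615).

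Immune genes were lower in breast muscle. The choice among 4 scalings did not remove the fall, since the macrophage median stayed at -1.16 or lower under each. All 4 are relative and none has an external standard, so a shift in RNA composition could not be tested. Breast scale factors separated the diets, with controls between 1.02 and 1.25 and deficient libraries between 0.791 and 0.992. A loss of every non-muscle cell type alike was excluded, because the macrophage score changed by -1.08 more than the endothelial score (n = 5 each, exact permutation p = 0.00794). Fewer leukocytes in the muscle may be the reason and cannot be told apart from lower expression per cell: the 19 markers all went down, with an SD of 0.378 between their log2 changes against a median standard error of 0.177, and no cells were counted.

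Oxidative and contractile genes were higher in breast muscle. The choice of scaling did not remove the rise, with a lowest oxidative phosphorylation median of 0.16 over 4 scalings. As these are all relative, a shift in RNA composition could not be tested. A bias by gene length was excluded, with a median of 0.49 after removal of the length trend. A larger share of muscle fibre RNA may contribute and cannot be told apart from regulation within fibres. The oxidative phosphorylation score changed by -0.21 relative to the fast contractile score (n = 5 each, exact permutation p = 0.0476), so both rose, by different amounts.

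In liver, some genes of stress and fasting such as TSC22D3 and UBB were lower on the deficient diet, without a call. Muscle RNA in control livers was excluded for these genes, as it supplies at most 0.970% of the excess of UBB and 0.335% of that of TSC22D3. Other genes were not checked for it. A lower stress hormone state at sampling is a candidate explanation: separate glucocorticoid targets had a median of -0.46, with 9 of 14 lower (n = 5 each, exact permutation p = 0.0317, camera adjusted p = 0.0882, and p = 0.153 with an estimated correlation). In breast muscle they were lower as well (median -0.46, 9 of 11 lower, exact permutation p = 0.0238, camera adjusted p = 0.0882, and p = 0.179 with an estimated correlation). The values are weak, TSC22D3 was not called in breast muscle (0.04), and handling cannot be separated from diet. UBB and the muscle-wasting list were lower in liver (-1.12 and a median of -0.17) but higher in breast muscle (0.93 and 0.42). A fed state stays open, with a fasting minus feeding score of -0.56 (n = 5 each, exact permutation p = 0.230) in which separate feeding genes had a median of 0.36 and fasting genes one of 0.04.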

How the results depend on the processing

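The tests without short features, without liver control 4 and liver deficient 1, by permuted list score and by leave-outs of the correlation were chosen after seeing the data. For named breast genes under settings with all libraries, 2693 gene and setting pairs kept direction and side of the threshold, 140 lost the call, 45 gained it and 5 uncalled values changed sign. For named liver genes 704 pairs did so, 4 gained a call and 4 uncalled values changed sign. Leave-outs gave 1804 (without breast control 2) to 3114 (without breast deficient 5) breast genes, 0 to 11 liver genes (11 without liver control 3), 23 to 28 breast lists, and 2 (without liver control 1) to 13 liver lists (without liver control 2; 12 without liver deficient 2). They gave 472 (without breast control 2) to 1143 (without breast deficient 5) genes for the tissue difference, with 553, 558 and 525 without breast control 4, deficient 3 and deficient 4, and correlations of 0.0363 (without liver control 5) to 0.124. Without scaling 11 liver lists and 1871 tissue-difference genes were called. Liver genes numbered 2 with no filter, 1 with a filter at 5 FPKM, 2 at the isoform level and 1 at adjusted p under 0.1. Tissue-difference genes numbered 557 with the filter at 5 FPKM, which tests fewer genes, and 1426 at adjusted p under 0.1. With a 1.5-fold minimum 1194 breast genes passed. Camera with an estimated correlation called 0 lists in either tissue. Fry by its directional p and the permuted score called 0 in liver, against 849 liver genes at unadjusted p under 0.05 in limma. The mitochondrially encoded list of breast muscle reversed under quantile normalization, with a statistic of -0.0587. Except for the changed thresholds and the filter, the cause was not tested. Without features under 200 nt there were 2907 breast, 0 liver and 851 tissue-difference genes, and without liver control 4 and deficient 1 there were 0 liver genes, 8 liver lists and 570 tissue-difference genes.

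Same-number libraries of the diets were no pairs by correlation of residuals (-0.066 to 0.091 in breast, -0.198 to 0.057 in liver). Same-number breast and liver libraries of a diet correlated at 0.0658 to 0.177 in controls and 0.00955 to 0.211 on the deficient diet. Medians for other numbers were -0.0312 and -0.0228. Same-number libraries were mutual best matches in 3 of 5 and 4 of 5 cases, so shared numbers may mark shared birds. With 5 birds per diet in the labels, both tissues would come from the same birds. The main fit of the tissue difference and the permutation of the correlation took the libraries as independent. With the number as a replicate block across diets the counts were 2064 breast and 0 liver genes, 26 breast lists and 6 liver lists. With the breast and liver libraries of a diet and number taken as 1 bird there were 1070 tissue-difference genes. The setting that keeps the entry with the highest mean was not run, because no identifier had more than 1 entry. No read counts were given, so the effect of depth on single genes was not estimated.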

Other observations

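Several lists held called genes in breast muscle without being called by camera, and their members went both ways. Over all genes tested 12.9% were called higher and 14.6% lower, and some of these lists lay near both shares. In the glutathione list 7 of 23 genes fell and 2 rose, with GGT5 at -0.71, GSTT1 at 0.75 and the 2 identifiers of GSTA3 at -1.97 and 0.95 (adjusted p = 0.121). Of 24 antioxidant genes 5 rose, such as PRDX3 (0.76) and MSRB3 (0.46), and 6 fell, such as TKT (-1.11) and PGD (-0.66) (0.906). Of 26 amino acid response genes 7 rose, such as SESN1 (1.35), and 5 fell, such as CEBPB (-1.43), JDP2 (-0.95) and SLC38A2 (-0.85) (0.684). Of 24 glycolysis genes 8 rose, with PFKM at 1.11, and 4 fell, with ALDOC at -1.30 (0.629). Of 35 ER stress genes 2 rose, HSPA9 (0.66) among them, and 7 fell, such as P4HB (-0.51) (0.0517). The gluconeogenesis list had 4 of 9 genes higher, with FBP2 and GOT1 (0.83), and 1 lower, FBP1 at -0.85 (0.0903). The autophagy list had 8 of 32 higher, with TFEB at 0.55, and 2 lower, CTSB (-0.85) and CTSD (-0.43) (0.0723).

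The transsulfuration list had 2 of 8 genes higher (CTH and GADL1, 0.157, with the GADL1 call ending without any of 6 libraries, breast control 2 at adjusted p = 0.0902 among them) and the methionine cycle list 4 of 19 higher and 1 lower, AHCYL1 at -0.40 (0.321). The other breast lists not called, with genes higher and lower and adjusted p, were ribosomal proteins (0 and 0 of 62, 0.121), coagulation (0 and 3 of 15, 0.269), adipocyte (1 and 2 of 13, 0.274), circadian (2 and 1 of 11, 0.327), erythroid (1 and 1 of 9, 0.440), purine (4 and 3 of 18, 0.493), IGF and mTOR (4 and 4 of 30, 0.494), xenobiotic (1 and 2 of 10, 0.818), cholesterol (1 and 0 of 18, 0.906), lipogenesis (2 and 4 of 26, 0.906), polyamine (2 and 2 of 18, 0.960), endothelial (1 and 2 of 20, 0.963) and myogenesis (3 and 2 of 23, 0.963). Median and mean differed in sign for the IGF, amino acid response, xenobiotic, cholesterol, antioxidant, endothelial and myogenesis lists. The exact permutation of the list score called autophagy, gluconeogenesis, transsulfuration and purine (adjusted p = 0.0196 each) and the methionine cycle (0.0448). Without scaling the medians of the autophagy, transsulfuration, purine and methionine cycle lists were negative (-0.11, -0.06, -0.11 and -0.19), yet each stayed above the median of all genes at -0.25.

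The 43 liver lists not called had camera adjusted p between 0.0763 for ER stress and 0.984 for antigen presentation. They included macrophage (0.897), heterophil (0.145), hepatocyte (0.767), cholangiocyte (0.180), thrombocyte (0.767), methionine cycle (0.767), transsulfuration (0.768), amino acid response (0.180), circadian (0.313), lipogenesis (0.731) and fatty acid oxidation (0.826). Too few pancreatic acinar genes were tested in either tissue, and too few thrombocyte and cholangiocyte genes in breast muscle.

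Besides the glucocorticoid targets, further lists written after the data were seen were tested in addition. Separate heat shock genes were lower in liver for 13 of 14, with a median of -0.43 (camera adjusted p = 2.39e-05, p = 0.113 with an estimated correlation, exact permutation p = 0.0476), and did not differ in breast muscle (exact permutation p = 0.786). Feeding-induced genes had a liver median of 0.36 (camera adjusted p = 0.0298, p = 0.241 with an estimated correlation, exact permutation p = 0.214), and fasting-induced genes 0.04 (exact permutation p = 0.651).

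Regrouping the libraries, up to 100 ways per result, asked whether chance groupings give results as large. For breast genes chance was excluded: 1 of 100 groupings, the real one, reached 2805, and the highest other gave 1. For breast lists chance was not excluded, as 7 of 100 reached 25, with a highest other of 27 and a median of 12. For liver lists chance was not excluded, as 91 of 100 reached 6, with a highest other of 20 and a median of 13. For liver genes the regrouping tests nothing, since the real count was 0 in limma, against 849 genes at unadjusted p under 0.05, and 100 of 100 groupings must reach it (highest other 2). For the tissue difference 1 of 100 reached 839, with a highest other of 521 that kept the real breast grouping. An earlier draw, replaced after its result was seen, had a highest other of 837. With the breast grouping kept and liver regrouped, 53 of 100 groupings reached 839, the others lying between 554 and 1692 with a median of 875. The size of the count thus depends on the breast grouping and is no evidence for or against a diet effect in liver.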
